A study of Homo sapiens with 30 samples.

How the data were processed

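RNA was measured in 30 libraries of 293FT cells transfected with plasmids and collected 3 days later, in 10 groups of 3. The authors aligned the reads with HISAT2 and counted them per gene with HTSeq on hg38, and the deposited values are raw counts per gene name with no normalization. The versions, the annotation release and the strand setting were not stated, so reads that overlap a gene on the opposite strand are not told apart where the setting was unstranded. The files hold 59385 gene names and, for each library, the totals of reads given to no gene. The unit was checked on the values, which are whole numbers.

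Groups were taken from the labels. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 23183. Counts were scaled with TMM factors and fitted in a single layout of 10 groups with robust quasi-likelihood dispersions, with 20 residual degrees of freedom and a common biological coefficient of variation of 12.1%. Each comparison was a contrast of 2 groups in that fit, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05, and genes with an absolute log2 fold change of at least 1 were counted beside it. Levels are TMM-scaled CPM (counts scaled to a library of 1e+06). The precision of each value comes from the spread of 3 libraries, and no interval for counting error alone is given.

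The 17 comparisons, their tests, 25 gene lists and the rule for naming genes were fixed before the data were examined, and so were the alternatives except those named here. For Cas9, Cas13a, Cas13b and Cas13d against Vector the rule takes, among genes with an adjusted p under 0.05, a mean of at least 5 CPM and all 3 test libraries on the same side of all 3 control libraries, the 6 highest and 6 lowest log2 fold changes, and for other comparisons 3 and 3. For every list called it adds up to 3 members with the smallest adjusted p in the direction of the call, and for lists not called up to 2 members past the threshold. Only some of the genes that the rule names are printed. A gene outside the rule is printed where its level is compared across groups, and those genes were chosen after their values were seen.

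The lists cover the interferon response, immediate-early genes, p53 targets, the integrated stress response, the unfolded protein response, heat shock, cytosolic and mitochondrial ribosomes, nuclear and mitochondrial genes of oxidative phosphorylation, replication-dependent histones, transcripts sensitive to nonsense-mediated decay, RNA decay, ribosome biogenesis, the spliceosome, G1 to S, G2 and M, cholesterol synthesis, hypoxia and glycolysis, NF-kB, the proteasome, KRAB zinc fingers, and markers of blood, fibroblasts and liver. With a list of plasmid parts that was not tested, they hold 749 entries. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Of 500 list tests 199 were called and 32 held with an estimated correlation.

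Alternatives were DESeq2 1.42.0, RLE factors in edgeR, no filter on low counts, a filter at a mean of 5 CPM, the replicate number as a block, only the 6 libraries compared, and each library left out in turn. After seeing the data 3 comparisons between Cas13 families, the interaction of crNT with DR, and a fit without 3 libraries were added. Those 3 libraries are Cas13a_DR replicate 2 and dCas13a_HR replicate 1, apart from their groups on the first principal component (10.6% of the variance), and dCas13a_R replicate 1, which had the fewest counts. Cas13a replicate 1 also lay apart from its group on that component (-25.9 against 8.97 and 12.9) and was kept in this fit. Added after seeing the data as well was a test of the liver list without each Cas13a_DR library in turn.

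The steps were tested on simulated data, drawn as negative binomial counts with the means and dispersions of this fit. Of abundant genes changed 1.25, 1.5, 2 and 3 times, edgeR recovered 20%, 60%, 90% and 100%, and 2.88% of the genes called had not been changed. With no gene changed 0 were called, and camera called 1 of 1 raised list and 0 of 20 random lists. Genes were drawn independently and with the same dispersion in every group, so no genes moved together and no library stood apart. The simulation therefore does not show how often camera at the preset correlation, or the joint fit, calls falsely in these data. Positions come from GENCODE on GRCh38 and were found for 290 of 303 named genes by symbol. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used. The reads and the plasmid sequences were not used here, and some genes are not reported here.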

Results

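RNA was sequenced from 293FT cells, a line derived from human embryonic kidney, 3 days after transient transfection with a plasmid for Cas9, for a Cas13 protein or for no effector. Cas9 is a CRISPR nuclease that cuts DNA, and Cas13a, Cas13b and Cas13d belong to CRISPR families that cut RNA. The 30 libraries formed 10 groups of 3, named Vector (the empty backbone), Cas9, Cas13a, Cas13a_DR, dCas13a_H, dCas13a_R, dCas13a_HR, Cas13b, Cas13b_crNT and Cas13d. The labels do not spell out DR, H, R, HR or crNT, and the prefix d is the field's usual mark for a nuclease-inactivated protein. Gene counts per library, in units of 1e+06, ran from 32.3 to 85.9, and 28304 to 33902 genes had at least 1 count in a library. Each comparison asked which transcripts differ after 3 days between cells that received different effector plasmids.

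Levels are given as CPM, the library-scaled count per 1e+06 counts, ± SD over the 3 libraries of a group, and log2 fold changes as fitted values ± SE. Adjusted p-values come from edgeR's quasi-likelihood test with the Benjamini-Hochberg correction over 23183 genes. The labels do not say that the 3 libraries of a group came from separate cultures, so these p-values measure only the spread between these samples. For any gene taken alone, an exact two-sided permutation test of 3 libraries against 3 cannot give a p below 0.1. The files identify genes by symbol only.

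Against Vector, the number of genes past an adjusted p of 0.05 in the joint fit of all 30 libraries ranged from 342 in dCas13a_H to 3164 in Cas13b_crNT. Most of these changes were small: a log2 fold change of at least 1 in size was met by 64 genes in dCas13a_H and 211 in Cas13b_crNT. Genes that recur below include FOSB and EGR1, transcription factors induced within minutes by growth factors and stress, IFIT1, an interferon-induced antiviral protein, and HSPA6, an inducible chaperone. On GRCh38, FOSB lies on chromosome 19 at 45467995 to 45475179, EGR1 on chromosome 5 at 138465490 to 138469315, IFIT1 on chromosome 10 at 89392546 to 89406486, and HSPA6 on chromosome 1 at 161524540 to 161526910. No exon of another gene overlaps any of these 4 in the annotation used, while NR4A1 and DDIT4, also named below, are each overlapped by an exon of a gene on the opposite strand.

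**Figure D1:**
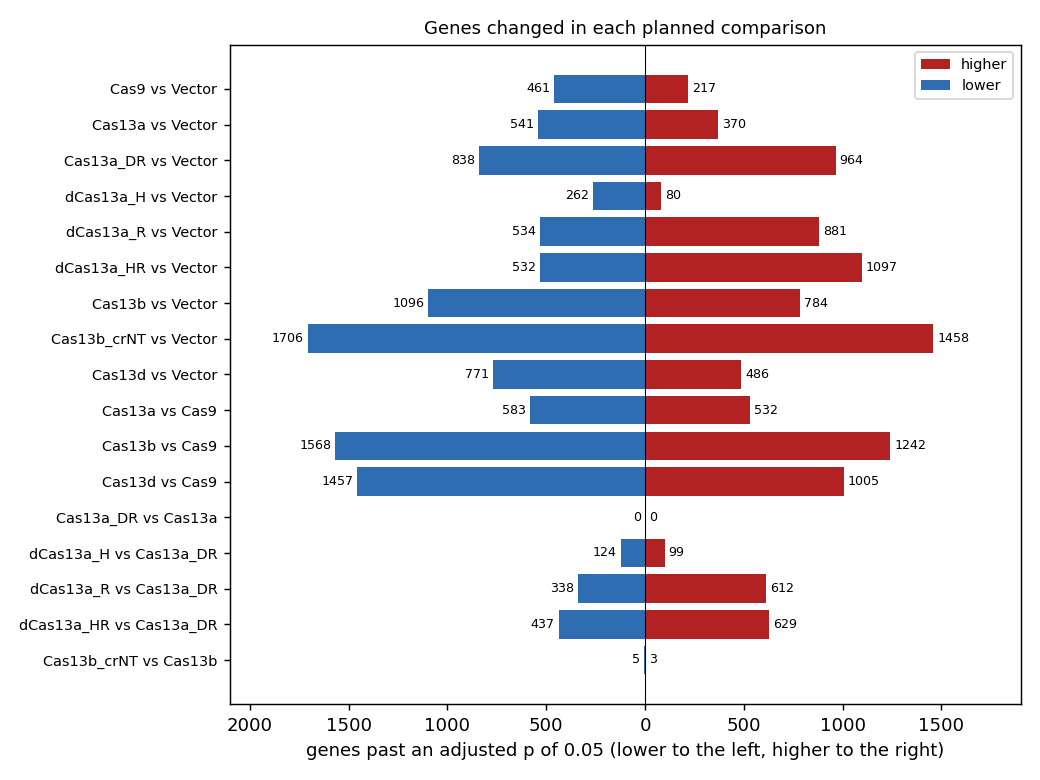
Number of genes past an adjusted p of 0.05 in each of the 17 planned comparisons, with lower genes drawn to the left of 0 and higher genes to the right. The bars run from 0 genes for Cas13a_DR vs Cas13a to 1706 lower and 1458 higher genes for Cas13b_crNT vs Vector.

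**Figure D2:**
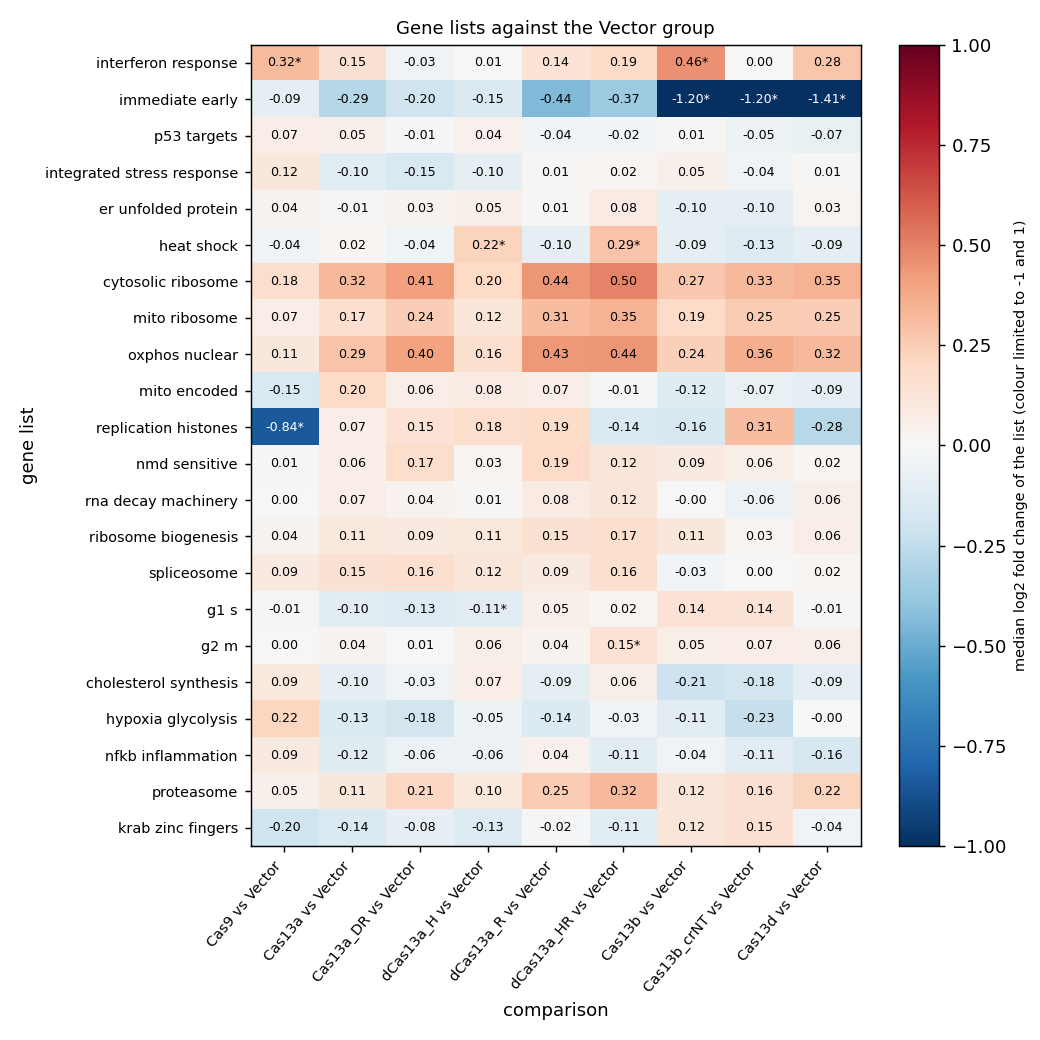
Median log2 fold change of the members of 22 gene lists (vertical axis) in the 9 comparisons with Vector (horizontal axis), as colour and as printed value. An asterisk marks a camera call at an adjusted p under 0.05 that also held with an estimated correlation, such as the immediate-early list in Cas13b (-1.20) and in Cas13d (-1.41).

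Cas9 changed 678 genes against Vector, 217 higher and 461 lower. DDIT4, a stress-induced inhibitor of mTOR signalling, rose by a log2 fold change of 1.00 ± 0.16, from 78.0 ± 6.03 to 156 ± 39.0 CPM. Of 24 measured interferon response genes 5 rose, 6 when adjusted over the list alone, among them IFIT1 (0.64 ± 0.09), IFIT3 (0.70 ± 0.16) and IFIT2 (0.73 ± 0.17), and camera called the list higher (adjusted p = 3.5e-06, and 0.034 with an estimated correlation). Of 30 measured replication-dependent histone genes, which package newly made DNA, 12 fell and 0 rose, 19 falling when adjusted over the list alone. H2AC11 fell by 1.39 ± 0.16, H2BC21 by 0.97 ± 0.13 and H2BC12 by 0.67 ± 0.08, and camera called this list lower (adjusted p = 1.9e-18, and 0.00013 with an estimated correlation). Histone counts were low throughout, which limits every result on this list. The mean log2 CPM of its members ran from -1.13 in Cas9 replicate 2 to 0.607 in Cas13b_crNT replicate 3 over the 30 libraries. DNAI4, a dynein subunit of motile cilia, was lower (-1.44 ± 0.11), and so was HSPA6 (-2.46 ± 0.30, 1.11 ± 0.199 against 6.07 ± 0.0166 CPM).

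KRAB zinc finger genes, DNA-binding repressors, were called lower by camera in Cas9, with 6 of 39 falling (camera adjusted p = 1.0e-07), with ZNF92 at -0.64 ± 0.11 and ZNF84 at -0.46 ± 0.09. That call was lost with an estimated correlation (adjusted p = 0.20). Members of the integrated stress response list went both ways in Cas9, with 5 higher, including PSAT1 (0.36 ± 0.07) and MTHFD2 (0.28 ± 0.06), and 2 lower (adjusted p = 0.0063, and 0.40 with an estimated correlation). Of the 23 immediate-early genes 0 passed in Cas9 by edgeR, and the list had a median of -0.09 (adjusted p = 0.22). The 678 genes became 365, 274 or 397 without Vector replicate 1, 2 or 3, and 311 or 262 without Cas9 replicate 1 or 2. The excess of lower genes was not kept by the 6 compared libraries alone (2058 higher and 1759 lower) or without 3 libraries that stood apart (821 and 849).

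Cas13a changed 911 genes against Vector, 370 higher and 541 lower. TCHH, a structural protein of hair follicles, rose most among the genes that met the naming rule (1.75 ± 0.14), from 4.35 ± 0.406 to 14.6 ± 2.01 CPM, followed by CHRM4, a muscarinic receptor (0.95 ± 0.17), and LHX2, a homeobox factor (0.77 ± 0.10). EGR3 (-1.61 ± 0.22), DNAH17 (-1.45 ± 0.15), EGR1 (-1.34 ± 0.24), EGR2 (-1.16 ± 0.17) and NR4A1 (-1.08 ± 0.12) fell. Of 23 immediate-early genes 10 fell and 0 rose, 13 falling when adjusted over the list alone (adjusted p = 8.4e-16, and 0.19 with an estimated correlation). Among 30 genes of the G1 to S transition 8 fell and 3 rose (adjusted p = 0.00026, and 0.19 with an estimated correlation), and EXO1, MCM4 and DTL, which act in DNA replication and repair, fell by 0.50 ± 0.06, 0.40 ± 0.05 and 0.41 ± 0.06. HSPA6 was at 0.349 ± 0.349 CPM in Cas13a, a log2 fold change of -4.09 ± 0.35, and GADD45A, listed as sensitive to nonsense-mediated decay, rose by 0.60 ± 0.09. INSIG1, which restrains cholesterol synthesis, fell by 0.70 ± 0.12, and VEGFA, a hypoxia-induced growth factor, by 0.51 ± 0.07. The 911 genes became 428, 524 or 455 without Vector replicate 1, 2 or 3, and 501 without Cas13a replicate 2. Without the 3 libraries that stood apart 1258 were higher and 1071 lower.

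Cas13a_DR changed 1802 genes against Vector, 964 higher and 838 lower. TCHH was again higher (1.47 ± 0.14, 12.02 ± 0.803 CPM), DNAH17 fell by 1.43 ± 0.15, and HSPA6 by 4.13 ± 0.35. GADD45A rose by 0.75 ± 0.09. Of the 23 immediate-early genes 5 fell, with NR4A1 at -0.77 ± 0.12 and EGR2 at -0.86 ± 0.17 (adjusted p = 2.9e-05, and 0.45 with an estimated correlation). G1 to S genes fell in 10 of 30 and rose in 3, led by EXO1 (-0.59 ± 0.06), MCM4 (-0.50 ± 0.05) and MCM3 (-0.44 ± 0.06), with an adjusted p of 8.0e-06, and 0.16 with an estimated correlation. The 1802 genes became 926, 1130 or 783 without Vector replicate 1, 2 or 3, and 964 without Cas13a_DR replicate 2, and a fit of the 6 compared libraries alone gave 2. More genes were lower than higher in each of these 4 fits without 1 library (353 higher and 611 lower without Cas13a_DR replicate 2) without the 3 libraries that stood apart (463 and 731) and with no filter on low counts (1065 and 1093).

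Cas13a_DR and Cas13a did not differ in any gene by edgeR's adjusted p: 0 genes passed, 1035 had an unadjusted p under 0.05 where 1159 are expected by chance, and DESeq2 called 1 gene. With no filter on low counts, 113 genes passed. A count below chance can arise where the fitted spread is too wide, and Cas13a_DR replicate 2 and Cas13a replicate 1 each lay apart from their group. The 0 genes therefore do not show that Cas13a_DR and Cas13a are alike. TCHH, at 12.02 CPM in Cas13a_DR and 14.6 in Cas13a, had a log2 fold change of -0.28 ± 0.14 between them, and RNU6-1, the U6 small nuclear RNA, one of -0.92 ± 0.22. The immediate-early list had a median of 0.19 between the groups, with 0 of 23 members passing (adjusted p = 8.3e-10, and 0.33 with an estimated correlation).

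The dCas13a_H group differed from Vector in 342 genes, 80 higher and 262 lower, the fewest of the 9 groups in the joint fit but not with the 6 compared libraries alone, where it gave 1612 against 2 for Cas13a_DR, 641 for Cas13a and 1077 for dCas13a_HR. HSPA6 rose by 1.53 ± 0.27, to 17.5 ± 1.45 CPM, and its co-chaperone DNAJB1 by 0.52 ± 0.06. Of 16 heat shock genes 5 rose and 0 fell, 9 rising when adjusted over the list alone, and camera called the list higher (adjusted p = 1.5e-14, and 0.00069 with an estimated correlation). The G1 to S list was called lower, with 3 of 30 falling and 12 when adjusted over the list alone: EXO1 fell by 0.57 ± 0.06, DTL by 0.39 ± 0.06 and CDC6 by 0.37 ± 0.06 (adjusted p = 3.8e-08, and 0.019 with an estimated correlation). ZNF441 fell by 1.05 ± 0.16. Every library left out in turn moved the 342 genes by more than 1.5 times, to 187, 180 or 158 without Vector replicate 1, 2 or 3, and to 146, 186 or 185 without dCas13a_H replicate 1, 2 or 3.

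The dCas13a_R group changed 1415 genes against Vector, 881 higher and 534 lower. EGR1 (-1.68 ± 0.24), EGR3 (-1.64 ± 0.22), EGR2 (-1.51 ± 0.17) and NR4A1 (-1.20 ± 0.12) fell, and 12 of 23 immediate-early genes fell in all (adjusted p = 3.3e-15, and 0.24 with an estimated correlation). CHRM4 rose by 1.02 ± 0.17. HSPA6, at 0.314 ± 0.156 CPM in this group, fell by 4.17 ± 0.36. PDXDC1 rose by 1.18 ± 0.35. The 1415 genes became 309, 656 or 337 without Vector replicate 1, 2 or 3, and 839, 601 or 197 without dCas13a_R replicate 1, 2 or 3. The excess of higher genes was lost without Vector replicate 1 (151 higher and 158 lower) or 3 (153 and 184) and without dCas13a_R replicate 3 (97 and 100).

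The dCas13a_HR group changed 1629 genes against Vector, 1097 higher and 532 lower. Of 16 heat shock genes 7 rose and 0 fell, 10 rising when adjusted over the list alone, with DNAJB1 at 0.37 ± 0.06, HSP90AA1 at 0.36 ± 0.07 and DNAJA1 at 0.32 ± 0.08 (adjusted p = 1.1e-08, and 0.012 with an estimated correlation). The list of G2 and M phase genes, which drive mitosis, was called higher, with 3 of 34 rising and 10 when adjusted over the list alone, among them CCNB1 (0.29 ± 0.08) and KIF2C (0.21 ± 0.06), at an adjusted p of 1.3e-06, and 0.012 with an estimated correlation. Immediate-early genes fell in 13 of 23, with EGR3 at -1.66 ± 0.22 and FOSB at -1.32 ± 0.21 (adjusted p = 7.8e-18, and 0.064 with an estimated correlation). The 1629 genes became 292, 740 or 277 without Vector replicate 1, 2 or 3, and 261 without dCas13a_HR replicate 1. In 3 of these fits more genes were lower: 114 higher and 178 lower without Vector replicate 1, 93 and 184 without Vector replicate 3, and 112 and 149 without dCas13a_HR replicate 1.

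Set against Cas13a_DR, dCas13a_H differed in 223 genes, 99 higher and 124 lower. HSPA6 was higher by 5.66 ± 0.36 (17.5 against 0.345 CPM), CRYAB, a small heat shock protein, by 2.50 ± 0.32, and DNAJB1 by 0.66 ± 0.06, and 5 of 16 heat shock genes rose (adjusted p = 7.0e-14, and 0.00088 with an estimated correlation). TCHH was lower by a log2 fold change of -1.23 ± 0.14, FAM111B by -1.02 ± 0.10 and GPR19 by -0.83 ± 0.08. DNAH17 was higher (0.82 ± 0.15). The 223 genes became 374 or 499 without Cas13a_DR replicate 1 or 3, and 95, 71 or 43 without dCas13a_H replicate 1, 2 or 3. More genes were higher than lower without Cas13a_DR replicate 2 (124 and 93), without dCas13a_H replicate 3 (25 and 18) and without the 3 libraries that stood apart (210 and 135). Fitted on the 6 compared libraries alone, 2 genes passed.

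Between dCas13a_R and Cas13a_DR 950 genes differed, 612 higher and 338 lower. The G1 to S list was called higher, with 10 of 30 rising and 0 falling, led by MCM3 (0.53 ± 0.06), DTL (0.51 ± 0.06) and MCM4 (0.39 ± 0.05), at an adjusted p of 1.8e-09, and 0.015 with an estimated correlation. DNAH17 (1.15 ± 0.15) and RNU6-1 (1.29 ± 0.22) were higher, and TCHH was lower (-1.05 ± 0.14). Immediate-early genes went both ways, with 5 falling, including CCN2 (-0.53 ± 0.12), and 2 rising (adjusted p = 1.1e-06, and 0.76 with an estimated correlation). Left out in turn, Cas13a_DR replicates 1 and 2 gave 560 and 2841 genes, and dCas13a_R replicates 1, 2 and 3 gave 494, 527 and 461. Fitted on the 6 compared libraries alone, edgeR called 0 genes.

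Between dCas13a_HR and Cas13a_DR 1066 genes differed, 629 higher and 437 lower. HSPA6 rose by 4.57 ± 0.35, CRYAB by 2.10 ± 0.32 and DNAJB1 by 0.51 ± 0.06, and 6 of 16 heat shock genes rose (adjusted p = 2.3e-11, and 0.0028 with an estimated correlation). G2 and M phase genes rose in 4 of 34, including KIF2C (0.29 ± 0.06) and HMMR (0.31 ± 0.09), and the list was called higher (adjusted p = 7.6e-06, and 0.015 with an estimated correlation). MCM4 (0.49 ± 0.05) and MCM6 (0.39 ± 0.05) were among 8 of 30 G1 to S genes that rose while 1 fell (adjusted p = 1.3e-05, and 0.063 with an estimated correlation). TCHH fell by 0.93 ± 0.14 here too. Left out in turn, Cas13a_DR replicates 2 and 3 gave 2534 and 610 genes and dCas13a_HR replicate 2 gave 512, and the 6 compared libraries alone gave 1. With the filter at 5 CPM 430 were higher and 476 lower.

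Cas13b changed 1880 genes against Vector, 784 higher and 1096 lower. FOSB fell by 4.56 ± 0.25, from 275 ± 61.4 to 11.7 ± 2.49 CPM, EGR1 by 3.83 ± 0.27, from 782 ± 144 to 55.0 ± 10.1 CPM, EGR3 by 3.90 ± 0.25, FOS by 2.59 ± 0.19 and NR4A1, an orphan nuclear receptor, by 2.07 ± 0.13. Of 23 immediate-early genes 19 fell and 0 rose, 20 falling when adjusted over the list alone (adjusted p = 1.6e-48, and 0.0019 with an estimated correlation). IFIT1 rose by 1.16 ± 0.09, from 15.3 ± 0.736 to 34.1 ± 2.29 CPM, IFIT2 by 1.44 ± 0.17, OASL by 1.43 ± 0.17 and ISG15 by 1.01 ± 0.16. Of 24 interferon response genes 9 rose and 0 fell, 13 rising when adjusted over the list alone (adjusted p = 1.2e-10, and 0.0022 with an estimated correlation).

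Also in Cas13b, TCHH rose by 1.49 ± 0.14 and CCNE2, a cyclin of the entry into S phase, by 0.89 ± 0.11. Cholesterol synthesis genes fell in 8 of 24, with IDI1 at -0.73 ± 0.11 (adjusted p = 0.00021, and 0.18 with an estimated correlation). TTK, a mitotic checkpoint kinase, fell by 0.74 ± 0.08, and DCP2, which removes the cap of mRNAs, by 0.56 ± 0.07. RP5-1056L3.3 had most of its counts in Cas13b replicate 1 (14.9 ± 21.4 CPM over the group). The 1880 genes became 1151 or 1131 without Vector replicate 1 or 3, and 1239, 1010 or 1155 without Cas13b replicate 1, 2 or 3. The excess of lower genes was lost with the 6 compared libraries alone (2827 higher and 2738 lower) and without the 3 libraries that stood apart (1877 and 1745).

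**Figure D3:**
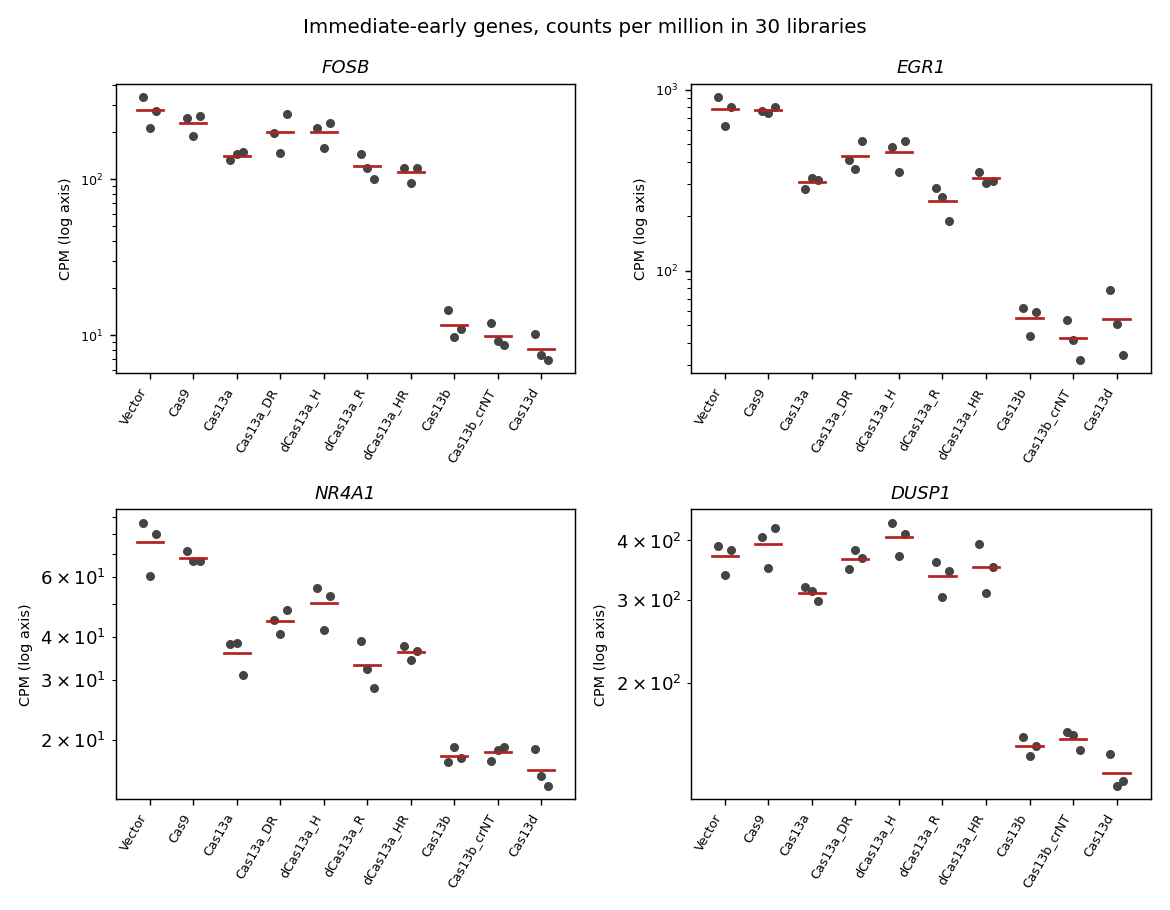
CPM on a log axis of FOSB, EGR1, NR4A1 and DUSP1 in the 30 libraries by group, with a dot per library and a line at the group mean. EGR1 had group means of 782 CPM in Vector and 771 in Cas9, 309 in Cas13a, and 55.0, 42.4 and 54.4 in Cas13b, Cas13b_crNT and Cas13d.

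Cas13b_crNT changed 3164 genes against Vector, 1458 higher and 1706 lower, the highest count of the 9 comparisons with Vector. FOSB fell by 4.80 ± 0.25, EGR1 by 4.21 ± 0.27 and EGR2 by 2.85 ± 0.18, and 20 of 23 immediate-early genes fell in all (adjusted p = 2.4e-38, and 0.0070 with an estimated correlation). RNU6-1 fell by 3.49 ± 0.24, from 301 ± 13.8 to 26.8 ± 1.5 CPM. TCHH rose by 1.56 ± 0.14. Of 30 replication-dependent histone genes 9 rose and 0 fell, among them H4C5 (1.63 ± 0.25) and H4C4 (2.03 ± 0.31), with an adjusted p of 0.0015, and 0.34 with an estimated correlation. ISG15 (0.80 ± 0.16) and IFIT1 (0.37 ± 0.09) were the 2 of 24 interferon response genes that rose, and camera did not call the list (adjusted p = 0.51). The 3164 genes became 2074 or 1929 without Vector replicate 1 or 3, and 1878 or 1854 without Cas13b_crNT replicate 2 or 3. More genes were higher than lower with no filter on low counts (1659 and 1562) and without the 3 libraries that stood apart (2626 and 2415).

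Between Cas13b_crNT and Cas13b 8 genes differed. IFIT1 fell by 0.78 ± 0.09, from 34.1 ± 2.29 to 19.8 ± 2.29 CPM, OASL by 1.19 ± 0.17 and IFIT2 by 1.02 ± 0.17, and with IFIT3 they made 4 of 24 interferon response genes, 13 when adjusted over the list alone. The list was called lower (adjusted p = 1.3e-23, and 1.9e-05 with an estimated correlation). RNU6-1 fell by 2.67 ± 0.23, from 170 ± 8.47 to 26.8 CPM. The other 3 genes, chosen here after their values were seen, were higher: SCRT1 (1.39 ± 0.21), XRCC6P1 (1.08 ± 0.19) and FOXJ1 (0.74 ± 0.14). Replication-dependent histone genes had a median log2 fold change of 0.45 and 10 of 30 rose when adjusted over the list alone, but 0 passed over all genes, and the list was called higher (adjusted p = 6.6e-16, and 0.00022 with an estimated correlation). The 8 genes became 5 without Cas13b replicate 2, and 5 or 4 without Cas13b_crNT replicate 1 or 2, while DESeq2 called 24 (16 higher) and no filter on low counts gave 94 (59 higher). The 6 compared libraries alone gave 146 higher and 66 lower, and 8 were higher and 7 lower without the 3 libraries that stood apart.

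Whether the crNT label moved genes in Cas13b as the DR label did in Cas13a was tested as an interaction. By edgeR 0 genes passed and 803 had an unadjusted p under 0.05, below the 1159 that chance gives. A count below chance can arise where the fitted spread is too wide, so 0 genes do not show that crNT and DR act alike. RNU6-1 ranked at the top, with effects of -2.67 for crNT and -0.92 for DR, a difference of -1.75 ± 0.31 and an adjusted p of 0.14.

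Cas13d changed 1257 genes against Vector, 486 higher and 771 lower. FOSB fell by 5.07 ± 0.25, from 275 to 8.19 ± 1.79 CPM, EGR3 by 4.24 ± 0.25, EGR1 by 3.85 ± 0.27, EGR2 by 3.39 ± 0.19, FOS by 2.93 ± 0.20, NR4A1 by 2.21 ± 0.13 and DUSP1, a phosphatase that switches off MAP kinases, by 1.52 ± 0.09. Of 23 immediate-early genes 22 fell and 0 rose (adjusted p = 2.2e-68, and 0.00023 with an estimated correlation). DDIT4 (0.82 ± 0.16), IFIT1 (0.75 ± 0.09) and ANXA1 (0.72 ± 0.09) rose. Interferon response genes rose in 5 of 24 and fell in 1 (adjusted p = 0.0052, and 0.36 with an estimated correlation). Among 21 p53 target genes 4 fell, including BTG2 (-0.63 ± 0.10), ZMAT3 (-0.40 ± 0.11) and MDM2 (-0.25 ± 0.08), with an adjusted p of 0.036, and 0.18 with an estimated correlation. TCHH had a log2 fold change of 0.33 ± 0.14 and did not pass. The 1257 genes became 606, 730 or 589 without Vector replicate 1, 2 or 3, and 628 or 622 without Cas13d replicate 2 or 3. Leaving out Cas13d replicate 1 gave 1595. The excess of lower genes was lost with the 6 compared libraries alone (897 higher and 851 lower) and without the 3 libraries that stood apart (1444 and 1385).

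Against Cas9, which asks how the RNA-directed effectors differ from a DNA-directed one, Cas13a changed 1115 genes, 532 higher and 583 lower. Replication-dependent histone genes rose in 16 of 30 and fell in 0, with H4C5 at 2.00 ± 0.30 and H2BC5 at 1.06 ± 0.14 (adjusted p = 2.0e-19, and 9.4e-05 with an estimated correlation). TCHH was higher (1.39 ± 0.14), and DDIT4 (-1.46 ± 0.16), EGR1 (-1.32 ± 0.24), INSIG1 (-0.95 ± 0.12) and NR4A1 (-0.93 ± 0.12) were lower. Immediate-early genes fell in 10 of 23 (adjusted p = 1.2e-11, and 0.14 with an estimated correlation), and 9 of 25 hypoxia and glycolysis genes fell, with VEGFA at -0.47 ± 0.07 (adjusted p = 2.4e-12, and 0.14 with an estimated correlation). The 1115 genes became 459 or 319 without Cas9 replicate 1 or 2, and 730 or 390 without Cas13a replicate 2 or 3, with 208 higher and 182 lower in the last. More genes were higher with RLE factors too (565 and 561), by DESeq2 (847 and 839) and with the 6 compared libraries alone (374 and 305).

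Cas13b differed from Cas9 in 2810 genes, 1242 higher and 1568 lower. Immediate-early genes fell in 19 of 23, with FOSB at -4.30 ± 0.24 (11.7 against 229 ± 34.4 CPM) and DUSP1 at -1.42 ± 0.09 (adjusted p = 6.4e-38, and 0.0036 with an estimated correlation). Histone genes rose in 19 of 30 (adjusted p = 2.0e-12, and 0.0020 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 24, among them SREBF2, a regulator of the pathway (-0.57 ± 0.08), and INSIG1 (-0.86 ± 0.12), at an adjusted p of 1.0e-07, and 0.032 with an estimated correlation. KRAB zinc finger genes rose in 18 of 39 and fell in 1, with ZNF202 at 0.52 ± 0.08 (adjusted p = 2.0e-12, and 0.033 with an estimated correlation). IFIT1 rose by 0.52 ± 0.09 above its Cas9 level and CCNE2 by 0.82 ± 0.11. The 2810 genes became 1864 or 1691 without Cas9 replicate 1 or 2, and 1661 without Cas13b replicate 2.

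Cas13d differed from Cas9 in 2462 genes, 1005 higher and 1457 lower. Immediate-early genes fell in 20 of 23, with FOSB at -4.81 ± 0.25 and CCN1 at -1.73 ± 0.10 (adjusted p = 2.3e-51, and 0.0014 with an estimated correlation). Histone genes rose in 13 of 30 (adjusted p = 3.9e-09, and 0.0052 with an estimated correlation), and cholesterol synthesis genes fell in 10 of 24, with SREBF2 at -0.68 ± 0.08 (adjusted p = 2.7e-06, and 0.049 with an estimated correlation). Of 21 p53 target genes 2 fell, BTG2 (-0.62 ± 0.10) and TNFRSF10B (-0.35 ± 0.08), 7 when adjusted over the list alone, and the list was called lower (adjusted p = 0.0020, and 0.016 with an estimated correlation). RN7SL1, the RNA of the signal recognition particle, rose by 1.49 ± 0.33. The 2462 genes became 1328 or 1054 without Cas9 replicate 1 or 2, and 885 or 946 without Cas13d replicate 2 or 3. Leaving out Cas13d replicate 1 gave 3336.

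**Figure D4:**
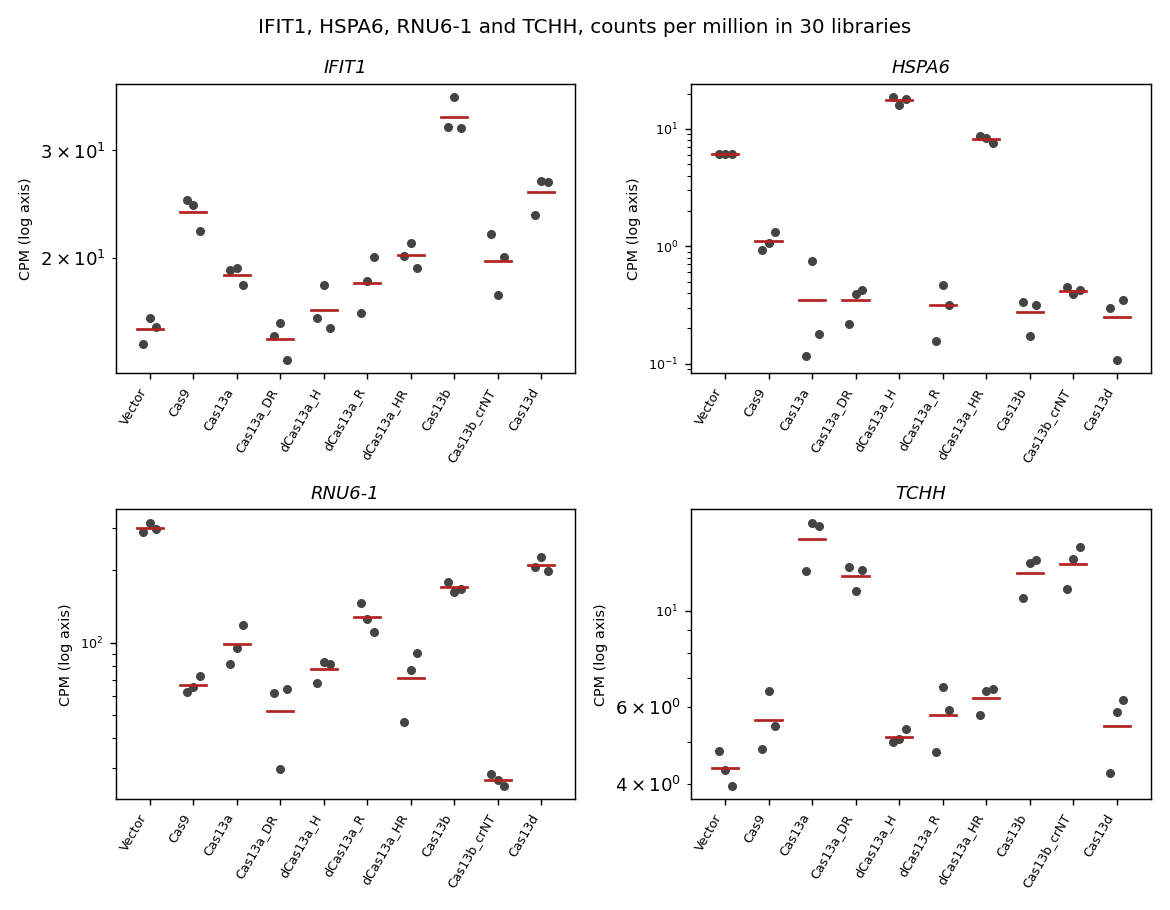
CPM on a log axis of IFIT1, HSPA6, RNU6-1 and TCHH in the 30 libraries by group, with a dot per library and a line at the group mean. TCHH had group means of 14.6 CPM in Cas13a and 12.2 in Cas13b against 4.35 in Vector and 5.44 in Cas13d, and HSPA6 of 17.5 in dCas13a_H and 8.26 in dCas13a_HR against 6.07 in Vector.

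Cytosolic ribosomal protein genes, 78 of which were measured, had positive medians in all 9 comparisons with Vector, from 0.18 in Cas9 to 0.50 in dCas13a_HR. In dCas13a_HR 67 rose, in dCas13a_R 54, in Cas13a_DR 39 and in dCas13a_H 0, and camera called the list in each (adjusted p from 3.9e-42 in dCas13a_HR to 3.2e-08 in Cas9). All 9 calls were lost with an estimated correlation (adjusted p = 0.099 in dCas13a_HR and 0.24 in dCas13a_R). Nuclear genes of oxidative phosphorylation rose in 38 of 69 in dCas13a_HR (adjusted p = 5.7e-31, and 0.12 with an estimated correlation), mitochondrial ribosomal protein genes in 19 of 38 (adjusted p = 1.9e-18, and 0.14 with an estimated correlation) and proteasome genes in 14 of 29 (adjusted p = 3.0e-17, and 0.099 with an estimated correlation). In Cas13a against Cas9 the cytosolic ribosomal list had a median of 0.15 and a mean of -0.03, and camera called it higher (adjusted p = 0.00063, and 0.62 with an estimated correlation). That mean includes RPS18, which was high in Cas9 replicate 2, as given below. RPL23A rose by 0.67 ± 0.12 in dCas13a_HR against Vector, NDUFB4 by 0.48 ± 0.09 and PSMC1 by 0.38 ± 0.07. The share of reads outside annotated features, 6.08% ± 0.208 in Vector, was lower in dCas13a_R (4.46% ± 0.0457) and dCas13a_HR (4.61% ± 0.541), and within groups the mean log2 CPM of the cytosolic ribosomal list fell by 0.20 ± 0.04 per percentage point of that share. That slope includes Cas13a_DR replicate 2, which lay apart from its group in both measures, and was not computed without that library. Without Cas13a_DR replicate 2, dCas13a_R replicate 1 and dCas13a_HR replicate 1 together, the direction of the cytosolic ribosomal list turned in Cas13a_DR against Cas13a and in dCas13a_H against Cas13a_DR, calls that had not held with an estimated correlation (camera adjusted p = 0.76 and 0.84).

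Smaller movements were seen in the remaining lists. Spliceosome genes rose in 12 of 39 in dCas13a_HR, with HNRNPC at 0.40 ± 0.07 (adjusted p = 2.5e-09, and 0.064 with an estimated correlation), ribosome biogenesis genes in 7 of 30, with NPM1 at 0.49 ± 0.09 (adjusted p = 1.2e-06, and 0.080 with an estimated correlation), and RNA decay machinery in 3 of 39, with EXOSC5 at 0.47 ± 0.10 (adjusted p = 0.0029, and 0.075 with an estimated correlation). Transcripts sensitive to nonsense-mediated decay rose in 5 of 22 in dCas13a_R, including SNHG15 (0.52 ± 0.12), at an adjusted p of 3.8e-05, and 0.24 with an estimated correlation. Genes of the unfolded protein response in the endoplasmic reticulum fell in 5 of 19 in Cas13d, with HERPUD1 at -0.51 ± 0.08, and camera did not call the list (adjusted p = 0.20). The 13 genes encoded in mitochondrial DNA rose in 3 in Cas13a against Cas9, including MT-ND5 (0.50 ± 0.13), at an adjusted p of 1.5e-05, and 0.24 with an estimated correlation. Of 19 genes of NF-kB signalling 4 fell in Cas13d against Cas9, with CSF1 at -0.61 ± 0.11 (adjusted p = 0.042, and 0.24 with an estimated correlation).

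RNU6-1, on chromosome 15 at 67839939 to 67840045, was highest in Vector at 301 ± 13.8 CPM and lowest in Cas13b_crNT at 26.8 ± 1.5. It lay at 66.6 ± 5.40 in Cas9, 98.4 ± 18.6 in Cas13a, 52.0 ± 19.3 in Cas13a_DR, 170 ± 8.47 in Cas13b and 211 ± 15.2 in Cas13d. The U6 promoter is a common part of guide-expressing plasmids, and the sequences of these plasmids were not used here. RPS18, a ribosomal protein gene, reached 872 CPM in Cas9 replicate 2 and at most 0.232 in any library outside Cas9, and its log2 fold change between Cas13b and Cas9 was -11.77 with all libraries and 1.05 without Cas9 replicate 2. Among markers of other cells, 5 of 8 liver markers were highest in Cas13a_DR replicate 3. As counts per 1e+06 without TMM factors, APOB lay there at 6.95 and at most 0.0914 in any other library, SERPINA1 at 3.28 and at most 0.0729, ALB at 7.16 and at most 2.52, TF at 3.79 and at most 2.66, and AHSG at 0.802 and at most 0.187. The other 3 were highest elsewhere, APOA1 in Cas13b_crNT replicate 1 (0.970), TTR in Cas13d replicate 1 (0.539) and FGB in dCas13a_R replicate 3 (0.224). Of the fibroblast markers COL1A1 had a median of 24.0 CPM and fell in Cas13b (-0.57 ± 0.12), Cas13b_crNT (-0.62 ± 0.12) and Cas13d (-0.54 ± 0.12) against Vector, and none of the 3 marker lists was called in these 3 comparisons. Against Cas9 the fibroblast list was called lower in Cas13a (adjusted p = 0.038, and 0.24 with an estimated correlation) and in Cas13d (adjusted p = 0.040, and 0.24 with an estimated correlation), and the liver list higher in Cas13d (adjusted p = 0.027, and 0.24 with an estimated correlation). The liver list was also called higher in Cas13a_DR against Cas13a (adjusted p = 0.0038, and 0.25 with an estimated correlation) and lower in dCas13a_H (adjusted p = 0.0037, and 0.17 with an estimated correlation) and dCas13a_HR (adjusted p = 0.013, and 0.24 with an estimated correlation) against Cas13a_DR. Without Cas13a_DR replicate 3 these 3 calls were lost (camera adjusted p = 0.34, 0.11 and 0.27), and they were kept without replicate 1 or 2.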

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

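Tests of library scaling, of shared handling, of the U6 promoter and of the Vector libraries were chosen only after the results they bear on were seen. The shares of reads that HTSeq gave to no gene lie outside the comparisons, and 12 group means are listed because every library of the group lay above the highest Vector library. Ambiguous reads, at most 7.38% in Vector, averaged 7.74% in Cas9, 7.77% in Cas13a, 7.78% in Cas13a_DR, 7.77% in dCas13a_R, 7.80% in dCas13a_HR, 7.92% in Cas13b, 8.01% in Cas13b_crNT and 7.82% in Cas13d. Reads not aligned, at most 6.65% in Vector, averaged 6.99% in dCas13a_H and 6.99% in dCas13a_R. The same share was lower than in every Vector library, at least 6.44%, in all libraries of the other 7 groups, with means of 3.33% in Cas13b, 3.36% in Cas13b_crNT, 3.87% in Cas9, 4.08% in Cas13a, 4.23% in Cas13d, 5.28% in Cas13a_DR and 6.02% in dCas13a_HR. Reads with more than 1 alignment, at most 5.82% in Vector, averaged 6.56% in Cas13b_crNT and 6.15% in Cas13d.

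Immediate-early genes were lower in Cas13b and Cas13d than in Vector. Library scaling is argued against, since a scale factor moves every gene alike and the list median less that of all genes was -1.19 in the comparison nearer 0, where the lowest of 1000 random lists of 23 genes gave -0.23. RNA quality read from the share of reads outside features is argued against as well, since the slope within groups plus 2 SE gave at most 0.594% of the difference. Handling shared by all libraries of a group stays open, because 0 labels name a batch, and it cannot be told apart from an effect of the effector proteins.

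RNU6-1 differed between groups, with 37 of the 45 pairs of groups not overlapping where chance gives 10%. Lower transcription of U6 genes in general stays open, because the other U6 genes tested lay near the floor. In Cas13b_crNT against Vector, where RNU6-1 fell by 3.49, RNU6-8 had a log2 fold change of 0.79 ± 0.38 (edgeR adjusted p = 0.18). RNU6-2 had one of -0.43 ± 0.66. Their levels in Vector were 0.538 and 0.0899 CPM, too low to decide. A candidate explanation is that reads from a U6 promoter or guide cassette on the plasmids were counted as RNU6-1, and without the plasmid sequences this stays open.

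Cytosolic ribosomal protein genes had positive medians against Vector in 9 comparisons, but all 9 camera calls were lost with an estimated correlation, and in dCas13a_H 0 of 78 members passed by edgeR. Transcript length and expression level are argued against only as the whole cause. In 9 of 9 the list median lay above the central 95% of 1000 lists matched on both, for example 0.50 against 0.22 to 0.29 in dCas13a_HR. Length and level may account for part, since the matched lists had a median of 0.13 in Cas9, where the list had 0.18, and of 0.25 in dCas13a_HR. The matched lists were drawn at random, so they lack the correlation between ribosomal genes, and the 9 comparisons share the Vector libraries. RNA quality read from the share of reads outside features may account for part, because the slope within groups gave at least 0.5 of the difference in 3 of 9 comparisons, 64.9% in Cas9, 71.2% in dCas13a_R and 60.1% in dCas13a_HR. The Cas9 value rests on a mean over members that includes RPS18, which was high in Cas9 replicate 2. The mean log2 CPM of the list was 9.36 in that library, against 9.17 and 9.19 in replicates 1 and 3. The 64.9% was not computed again without RPS18. The slope within groups also leans on Cas13a_DR replicate 2, with a share of 4.28% and a list mean of 9.84. Cas13a_DR replicates 1 and 3 had shares of 6.26% and 6.62% and list means of 9.16 and 9.07. The slope was not computed again without Cas13a_DR replicate 2, so all 3 percentages depend on that library. Low values in the shared Vector libraries stay open too, since against Cas9 the medians were 47.0%, 33.4% and 54.4% of those against Vector in Cas13a, Cas13b and Cas13d.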

How the results depend on the processing

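The fit without 3 libraries, and all alternatives for the comparisons between Cas13 families, were chosen after the data were seen. With RLE factors 20 of 20 counts of changed genes stayed within 1.5 times the reported one, and so did 20 of 20 with the replicate block. Replicate numbers did not pair the libraries: residuals of libraries with the same number had a mean correlation of 0.005 over 135 pairs, against -0.003 over 270 pairs with different numbers. For Cas9 against Vector, 674 of 678 genes were shared with RLE factors, 618 with the replicate block, 662 with DESeq2, 665 with only the 6 libraries and 678 without the 3 libraries, but only 414 with no filter on low counts, which called 703, and 487 with the filter at 5 CPM, which called 779. With 1 library left out 255 to 426 were shared. Other comparisons differed widely in this. With only the 6 libraries, 1856 of 1880 were shared for Cas13b and 2 of 1802 for Cas13a_DR against Vector. In that setting 0 of 950 were shared for dCas13a_R against Cas13a_DR and 219 of 1596 for Cas13d against Cas13a. Without the 3 libraries, 1880 of 1880 were shared for Cas13b and 849 of 1802 for Cas13a_DR against Vector.

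DESeq2 kept 11 of 20 counts within 1.5 times and gave more in the other 9: 1225 for Cas9, 1516 for Cas13a, 630 for dCas13a_H, 2270 for dCas13a_R and 1987 for Cas13d against Vector, 1686 for Cas13a against Cas9, 1 for Cas13a_DR against Cas13a, 567 for dCas13a_H against Cas13a_DR and 24 for Cas13b_crNT against Cas13b. Without a filter on low counts 4 rose by more than 1.5 times, to 2223 for dCas13a_R against Vector, 113 for Cas13a_DR against Cas13a, 588 for dCas13a_H against Cas13a_DR and 94 for Cas13b_crNT against Cas13b. With the filter at 5 CPM, which tests fewer genes, Cas13b_crNT against Cas13b gave 2. The cause was not tested for DESeq2 or the missing filter.

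Only the 6 libraries compared, a fit with fewer samples, gave more genes in 9 and fewer in 10 of 20, by more than 1.5 times in 7 and 7. Against Vector the counts that moved so far were 3817 for Cas9, 2 for Cas13a_DR, 1612 for dCas13a_H, 4669 for dCas13a_R, 1077 for dCas13a_HR, 5565 for Cas13b and 6629 for Cas13b_crNT. They were 679 for Cas13a and 6415 for Cas13b against Cas9, 2, 0 and 1 for dCas13a_H, dCas13a_R and dCas13a_HR against Cas13a_DR (by edgeR), 212 for Cas13b_crNT against Cas13b and 225 for Cas13d against Cas13a.

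Without Cas13a_DR replicate 2, dCas13a_R replicate 1 and dCas13a_HR replicate 1 the counts rose in 18 of 20 and fell in 1, by more than 1.5 times in 16 and 1. Here the cause was not tested either. Gene counts of replicates were compared in pairs by a chi-square per degree of freedom. It was 107 and 112 for pairs with Cas13a_DR replicate 2, and 38.5 and 42.1 for pairs with dCas13a_HR replicate 1. For dCas13a_R replicate 1 it was 6.46 and 13.5, for Cas13a replicate 1 31.2 and 42.2, and within Vector 5.66 to 9.18. For Cas13d replicate 1, which was kept in this fit, it was 34.4 and 27.3, against 10.5 between Cas13d replicates 2 and 3. The joint fit estimates its dispersions over all groups together, so its counts rest on a spread that the groups did not share. The counts past 1.5 times were, against Vector, 1670 for Cas9, 2329 for Cas13a, 1194 for Cas13a_DR, 929 for dCas13a_H, 3491 for dCas13a_R, 3622 for Cas13b, 5041 for Cas13b_crNT and 2829 for Cas13d. Against Cas9 they were 2448, 4446 and 4297 for Cas13a, Cas13b and Cas13d. The others were 345 for dCas13a_H and 3544 for dCas13a_R against Cas13a_DR, 15 for Cas13b_crNT against Cas13b, 3473 for Cas13b and 2903 for Cas13d against Cas13a, and 2003 for Cas13d against Cas13b. Without the 3 libraries the direction of 4 list calls turned: the cytosolic ribosome in Cas13a_DR against Cas13a, now lower (adjusted p = 6.8e-37 by camera), and in dCas13a_H against Cas13a_DR the cytosolic ribosome (7.9e-06), the mitochondrial ribosome (0.0070) and nuclear oxidative phosphorylation genes (0.023), now higher. None of these 4 calls had held in the full fit with an estimated correlation (adjusted p = 0.76 in the former comparison and 0.84 in the latter), which was not run without the 3 libraries.

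Leaving out 1 library in turn kept 42 of the counts within 1.5 times, lowered 74 and raised 4. Against Vector the counts ran from 262 to 488 for Cas9, 428 to 715 for Cas13a, 783 to 2530 for Cas13a_DR, 146 to 187 for dCas13a_H, 197 to 839 for dCas13a_R, 261 to 1535 for dCas13a_HR, 1010 to 1330 for Cas13b, 1854 to 2487 for Cas13b_crNT and 589 to 1595 for Cas13d. Against Cas9 they ran from 319 to 1065 for Cas13a, 1661 to 2234 for Cas13b and 885 to 3336 for Cas13d. Against Cas13a_DR they ran from 43 to 499 for dCas13a_H, 461 to 2841 for dCas13a_R and 512 to 2534 for dCas13a_HR. The range was 4 to 8 for Cas13b_crNT against Cas13b, 1456 to 2095 for Cas13b and 823 to 2016 for Cas13d against Cas13a, and 662 to 1296 for Cas13d against Cas13b. Cas13a_DR against Cas13a stayed at 0 by edgeR, with 1035 genes at an unadjusted p under 0.05 in the full fit. The log2 fold change of RPS18 in Cas13b against Cas9 ran from -17.02 to 1.05 and that of HSPA1B in Cas13d against Cas13a from -0.17 to 2.95.

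Of 199 list calls 32 held with an estimated correlation and 167 did not, 196 held with RLE factors, 195 with the replicate block, and 94 with fry, which tests whether a list moves on balance. Without the 3 libraries that stood apart 184 held, 11 were lost and 4 turned. Named gene values stayed past the threshold with DESeq2 in 833 cases, with RLE factors in 830 of 838, with the replicate block in 815 of 838, with only the 6 libraries in 598 of 836, with no filter on low counts in 759 of 838, with the filter at 5 CPM in 747 of 759 and without the 3 libraries in 792 of 838. With 1 library left out 3837 values stayed, 1189 did not pass and 2 changed sign. The smallest simulated change was recovered in 20% of genes and a change of 2 times in 90%, so small changes are often missed with 3 libraries a group.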

Other observations

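The comparisons between Cas13 families, the counts of overlap between effectors and the splits of the libraries were chosen after the data were seen. Cas13b differed from Cas13a in 2250 genes, 1072 higher and 1178 lower. FOSB fell by 3.60 ± 0.24 and EGR1 by 2.49 ± 0.25, and DDIT4 was higher, at 135 ± 7.66 against 56.7 ± 6.35 CPM. Immediate-early genes fell in 16 of 23 (camera adjusted p = 1.2e-28, and 0.012 with an estimated correlation), interferon response genes rose in 8 of 24 (camera adjusted p = 3.7e-07, and 0.012 with an estimated correlation), and G1 to S genes rose in 15 of 30 and fell in 3, with MCM4 at 0.49 ± 0.05 (camera adjusted p = 2.8e-10, and 0.012 with an estimated correlation). The 2250 genes became 1456 without Cas13b replicate 2. More genes were higher than lower with no filter on low counts (1066 and 1012) and by DESeq2 (1397 and 1363).

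Cas13d differed from Cas13a in 1596 genes, 736 higher and 860 lower, with FOSB at -4.12 ± 0.24, CCN1 at -1.42 ± 0.10 and DUSP1 at -1.26 ± 0.09. Immediate-early genes fell in 18 of 23 (camera adjusted p = 6.3e-45, and 0.0030 with an estimated correlation). HSPA1B, at 2.42 ± 0.71, changed sign without Cas13d replicate 3 (-0.17). The 1596 genes became 823 without Cas13a replicate 2, and 957 or 893 without Cas13d replicate 2 or 3. Leaving out Cas13d replicate 1 gave 2016. Fitted on the 6 compared libraries alone, 225 passed. With the filter at 5 CPM 918 were higher and 879 lower.

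Cas13d differed from Cas13b in 1169 genes, 587 higher and 582 lower, with TCHH at -1.16 ± 0.14 and LHX2 at -0.95 ± 0.10. Interferon response genes fell in 6 of 24, with IFIT1 at -0.41 ± 0.09 (camera adjusted p = 6.5e-07, and 0.018 with an estimated correlation), and G1 to S genes fell in 10 of 30 and rose in 2, with DTL at -0.44 ± 0.06 (camera adjusted p = 6.7e-08, and 0.018 with an estimated correlation). The p53 targets, of which 1 fell, were called lower (camera adjusted p = 0.0049, and 0.019 with an estimated correlation). The 1169 genes became 662, 676 or 700 without Cas13b replicate 1, 2 or 3, and 713 without Cas13d replicate 3. More genes were lower than higher with RLE factors (558 higher and 638 lower), by DESeq2 (719 and 948), without the 3 libraries that stood apart (987 and 1016) and without Cas13d replicate 1 (601 and 695) or 2 (390 and 400).

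Overlap between effectors was counted on comparisons with no library in common, one against Vector and the other against Cas9. Genes lower in both Cas13b against Vector and Cas13d against Cas9 numbered 277 where 68.9 were expected if the calls were independent, 157 were higher in both where 34.0 were expected, and 86 went opposite ways (96.8 expected). For Cas13d against Vector and Cas13b against Cas9 the counts were 230 (52.1 expected), 96 (26.0 expected) and 76 (74.2 expected). For Cas13a against Vector and Cas13b against Cas9, 74 were lower in both (36.6 expected), 40 higher in both (19.8 expected) and 152 opposite (54.0 expected), and for Cas13b against Vector and Cas13a against Cas9 the counts were 83 (27.6 expected), 51 (18.0 expected) and 78 (44.9 expected). For Cas13a against Vector and Cas13d against Cas9 they were 49 (34.0 expected), 37 (16.0 expected) and 123 (46.7 expected), and for Cas13d against Vector and Cas13a against Cas9 57 (19.4 expected), 27 (11.2 expected) and 62 (29.9 expected). Opposite calls thus exceeded their expectation in the 4 pairs with Cas13a and lay near it in the other 2. The expectation treats all genes alike, although abundant genes are called more easily in any comparison. An excess over it alone therefore does not show a shared response. Across 23183 genes, which are not independent replicates, the fold changes had correlations of 0.12, 0.17, 0.06, 0.02, 0.05 and 0.05 in these 6 pairs, in the order given.

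The 6 libraries of each comparison can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Every grouping but the real one mixes libraries of both groups, so a difference between the groups widens its spread and lowers its count. The counts of the other groupings therefore do not show what would come without a difference, and no conclusion is drawn from the contrast. Fitted on those 6 libraries alone, the real grouping and the highest of the others gave 3817 and 2 genes for Cas9 against Vector, 641 and 1 for Cas13a, 2 and 0 for Cas13a_DR, 1612 and 7 for dCas13a_H, 4669 and 1 for dCas13a_R, 1077 and 1 for dCas13a_HR, 5565 and 1 for Cas13b, 6629 and 2 for Cas13b_crNT, and 1748 and 2 for Cas13d. Against Cas9 they gave 679 and 1 for Cas13a, 6415 and 1 for Cas13b, and 2850 and 2 for Cas13d. Against Cas13a_DR they gave 2 and 1 for dCas13a_H, 0 and 0 for dCas13a_R and 1 and 1 for dCas13a_HR. Cas13a_DR against Cas13a gave 0 and 1, Cas13b_crNT against Cas13b 212 and 4, Cas13b against Cas13a 1841 and 1, Cas13d against Cas13a 225 and 1, and Cas13d against Cas13b 1138 and 2. As many genes as in the real grouping came from 10 of 10 for Cas13a_DR against Cas13a and dCas13a_R against Cas13a_DR, from 2 of 10 for dCas13a_HR against Cas13a_DR, and from the real grouping alone, 1 of 10, in the other 17.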
